A study of Mus musculus with 4 samples.

How the data were processed

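RNA was measured in 4 libraries of mouse embryonic fibroblasts (MEFs, primary connective tissue cells grown from whole embryos) on a C57BL/6 background. The genotypes compared were wild type and knockout of PIN1, a prolyl isomerase that acts on phosphorylated proteins, with 2 libraries each. Per the labels' protocols, passage 2 cells were grown in 10% serum to density arrest, split to 50% confluency, starved for 48 h in 0.2% serum and harvested 4 h after stimulation with 20% serum. No unstimulated library was analysed here, so every comparison is between genotypes after stimulation. The labels call the replicates independent experiments and do not say whether they came from separate embryos, so p-values measure the spread between these libraries.

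The deposited tables hold whole-number read counts per RefSeq transcript, 25481 rows per library, with coordinates on the mouse build mm9 per the labels. Per the submitters' processing notes, CASAVA 1.8.2 and Bowtie 1.0.0 were used. The counting tool, its strand rule and its treatment of reads that map to several places are not given in the sources used here. Each table also holds a scaled signal deposited by the authors, which equals the count times 1 constant factor per library. The factors were 2.63, 1.91, 1.60 and 1.28 and do not follow the sums of the counts exactly, so the scaled signal was used only as an alternative. Starts in the files count from 0, as 794 of 991 olfactory receptor rows shorter than 1100 bp have an end minus start that is a multiple of 3, against 102 with 1 added. Coordinates are printed 1-based.

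Transcripts of a gene repeat the same reads, so 1 row per gene symbol was kept, the row with the highest sum over the libraries, which left 20258 genes. Over these genes the libraries held 15567103 and 17701474 counts in wild type replicates 1 and 2, and 21999948 and 27601500 in knockout replicates 1 and 2. No pair of libraries held identical counts. Counting intervals at 95% confidence were taken from the exact binomial (Clopper-Pearson) interval of the summed counts, scaled by effective library size. They cover counting error only, since reads without molecular identifiers are not independent molecules.

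The main test was edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM scaling, robust dispersions and the quasi-likelihood F test, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The filter kept 12985 genes. Standard errors of log2 fold changes come from the quasi-likelihood F statistic. Expression per library is given as CPM, counts divided by the TMM-scaled library size on the usual per-megaread scale, with mean ± SD and n = 2. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and at least 5 tested members, two-sided. Camera was run again with an estimated correlation, and fry beside it. A list's median is over its members' differences in mean log2 CPM, and counts of higher and lower members use the sign of edgeR's fold change. The 45 lists, with 1703 members of which 1679 were found, were fixed before the data were examined, as were the comparison, its test and most alternatives. With 2 libraries against 2, an exact two-sided permutation test of a single value cannot go below p = 0.333, so none is given.

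The rule for named genes, fixed in advance, took Pin1 and Myc, up to 12 genes per direction past the threshold whose groups did not overlap and whose mean reached 5 CPM, and up to 4 members of smallest p per described list. No gene met its second part. A replacement was chosen after the values were seen: the same rule at an unadjusted p under 0.05, with 12 genes per direction, leaving out predicted genes. Genes called by DESeq2 1.42.0 are named as well, also chosen after their values were seen.

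The tests were tried on simulated counts drawn with the real means and library sizes, with 200 genes changed. With a biological coefficient of variation of 0.2, edgeR recovered 29.9% of 2-fold, 95.5% of 4-fold and 100% of 8-fold changes among 12821 genes. With the spread estimated from these libraries it recovered 0%, 3% and 19.7% among 12494 genes. At that spread DESeq2 recovered 50% of the 8-fold changes and also called 50 unchanged genes. A list shifted by 1 on the log2 scale had a camera adjusted p of 9.90e-24 at low spread and 0.187 at the estimated spread. Camera called 0 unshifted lists. Genes were drawn independently, so these lists held no correlation between members and do not test the preset correlation. Each gene had the same spread in all 4 libraries, so a single library that stands apart was not simulated.

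Alternatives were leaving out each library, the replicate number as a block, DESeq2 size factors, upper-quartile scaling, no filter, a filter of 5 CPM in 2 libraries, DESeq2, limma-voom, limma on log2 of the deposited scaled signal plus 1, and other thresholds. Other alternatives were added after seeing the data: a correction for transcript GC content and length (a spline with 5 degrees of freedom for each, per library), that correction with the block, the mean over a gene's transcript rows, and voom with library quality weights. GC content and length came from GENCODE vM21 transcripts matched by RefSeq accession or symbol for 20034 genes. No coordinate was taken from that reference. Alternatives meant for tables without counts did not apply. Tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots drawn with matplotlib 3.10.9.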

Results

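The data were gene counts from 4 RNA-seq libraries of serum-stimulated MEFs, 2 wild type and 2 PIN1 knockout. Wild type replicate 1 had the lowest total, 15567103 counts, and detected 11387 of 20258 genes. Wild type replicate 2 detected 14729 genes, and knockout replicates 1 and 2 detected 14617 and 15418. Across the 12985 tested genes, wild type replicate 1 correlated with the other libraries at r = 0.76, 0.822 and 0.738 in log2 CPM. The other 3 libraries correlated with one another at 0.919, 0.95 and 0.955. The first principal component held 87.7% of the variance and separated wild type replicate 1 from the rest. These are correlations across genes, which are not independent replicates. Because this library stands apart, the medians of the called gene lists are given against each wild-type library.

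The first comparison checked the genotype labels. Pin1 (NM_023371, mm9 chromosome 9, 20456574 to 20471028) was measured at 200 and 77.9 CPM in wild type replicates 1 and 2, and at 0.043 and 0.244 CPM in the knockout replicates. The counts were 2693 and 1454 against 1 and 7. Summed by genotype, 4147 against 8 counts gave an 838-fold lower level in knockout, with a 95% counting interval of 425 to 1940. The edgeR log2 fold change was −9.82 ± 1.20 (SE, n = 2 per genotype). Its Benjamini-Hochberg adjusted p over all genes was 0.9998. Adjusted over the list alone, the list being 28 peptidyl-prolyl isomerases, it was 0.0149. DESeq2 called it with an adjusted p of 4.80e-19. Pin1l (NM_001033768, mm9 chromosome 2, 104554083 to 104556447), a Pin1-like gene, had 203 and 147 counts in wild type and 0 and 1 in knockout. The ratio was 566, with a counting interval of 101 to 22400. It shares 9.84% of its 25-base words with Pin1 exactly and 46.52% with up to 2 mismatches, so its counts are uncertain as a measure of its own RNA.

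The second question was whether MYC RNA, which the serum step was meant to induce, differed by genotype. Myc (NM_001177352, mm9 chromosome 15, 61816896 to 61821916) had 577 and 4116 counts in wild type and 2591 and 3912 in knockout. The log2 fold change was −0.09 and its edgeR adjusted p was 0.9998, well within the spread between the wild-type libraries. The sign of the Myc difference depended on the wild-type library: it was −0.82 without wild type replicate 1 and 1.54 without wild type replicate 2, a fit in which edgeR called Myc higher in knockout (adjusted p = 0.0147). It was 0.07 without knockout replicate 1 and −0.24 without knockout replicate 2.

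The main comparison asked which genes differ between knockout and wild type after serum. Among genes with a mean of at least 5 CPM, the largest candidates included the 4 Y-linked genes, higher in knockout, and Pin1, Pin1l, Plin4, Comp, Eln and Aqp1, lower in knockout. None passed the main threshold. EdgeR's main fit called 0 of 12985 genes, and the smallest adjusted p was 0.9998. At an unadjusted p under 0.05 there were 166 genes (1.28%), of which 53 were higher and 113 lower in knockout. DESeq2 called 19 genes, 5 higher and 14 lower, and limma-voom called 0. In simulation at this spread, DESeq2 also called unchanged genes. That simulation gave all 4 libraries the same spread, whereas here wild type replicate 1 stands apart, so its rates may not carry over. With the replicate number as a block, edgeR called 32 genes, 14 higher and 18 lower, though replicate numbers are shared by label only. The groups did not overlap for 3468 genes (26.71%), where chance gives 33.3%. The common biological coefficient of variation was 0.741. Leaving out a wild-type library changed the count most: edgeR called 321 genes without replicate 1, of which 73 were higher and 248 lower. It called 6363 without replicate 2, a fit that compares the knockouts with replicate 1 alone, and there the balance was the opposite, with 4093 higher and 2270 lower. Without knockout replicate 1 or 2 it called 2 genes each.

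RNAs of the Y chromosome were present in both knockout libraries and nearly absent from both wild-type libraries. Ddx3y, an RNA helicase gene (mm9 chromosome Y, 597158 to 623056), had 3 and 2 counts in wild type and 1578 and 3341 in knockout. Its ratio was 608, with a counting interval of 261 to 1870. Eif2s3y, a translation initiation factor gene, summed to 3 counts in wild type and 2282 in knockout, a ratio of 470 (161 to 2280). Uty summed to 2 against 632 counts, a ratio of 195 (53.9 to 1620), and Kdm5d, a histone demethylase gene, to 6 against 738, a ratio of 76.1 (34.8 to 208). These genes came from a list for embryo sex, of Y-linked genes and Xist, with 9 members, 7 found and 4 tested. Xist was not among those tested. All 4 tested members passed when adjusted over the list alone, 0 passed over all genes in edgeR's main fit, and DESeq2 called 4. Y-linked RNA and genotype divided the 4 libraries in the same way.

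The other lower candidates were picked by size or by DESeq2, not as a gene group. Groups that did not overlap were required of those picked by size. Those picked by DESeq2 alone were also lower in both knockout libraries than in both wild-type libraries. Igfbp4, which binds insulin-like growth factors, averaged 987 ± 58.7 CPM in wild type and 144 ± 31.0 in knockout (SD, n = 2), a log2 fold change of −2.78 ± 0.50 (SE; DESeq2 adjusted p = 6.74e-04). Aqp1, a water channel, was at 179 and 318 CPM in wild type and 18.3 and 12.8 CPM in knockout, with a log2 fold change of −4.00 ± 0.61 (DESeq2 adjusted p = 9.85e-07). Serpina3g, a serine protease inhibitor, averaged 96.2 ± 4.22 against 8.37 ± 3.32 CPM. Anxa8, an annexin, averaged 96.5 ± 23.4 against 10.6 ± 0.264 CPM, and Kcnk3, a potassium channel, 37.9 ± 20.5 against 1.76 ± 0.914 CPM. S100a16, a calcium-binding protein gene, averaged 178 ± 101 against 22.9 ± 7.25 CPM. Rspo2, a Wnt pathway agonist, averaged 24.2 ± 22.1 against 0.686 ± 0.362 CPM. Plvap, known from endothelium, was at 32.2 and 5.95 CPM in wild type and 0.215 and 0.593 in knockout. Cnnm1 summed to 250 counts in wild type and 4 in knockout. DESeq2 called each of these, as it did Comp, Plin4 and Eln, and edgeR's main fit called none. Without wild type replicate 1, then without replicate 2, the log2 fold change was −2.83 and −2.71 for Igfbp4. In the same order it was −4.35 and −3.51 for Aqp1 and −3.56 and −3.46 for Serpina3g. It moved more for Rspo2 (−5.82 and −3.60) and Plvap (−3.83 and −6.26). Also among the 12 lower candidates of largest fold change with a mean of at least 5 CPM, and called by neither tool, were Krtap1-5 (log2 fold change −4.56 ± 1.61), Gpbar1, a bile acid receptor (−4.06 ± 1.18), and Slc1a3, a glutamate transporter (−3.93 ± 0.98). The log2 fold changes of Krtap1-5 and Slc1a3 were −1.91 and −2.54 without wild type replicate 2.

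Among candidates higher in knockout, Lrrc15, a membrane protein of activated fibroblasts, averaged 99.5 ± 11.4 CPM in wild type and 538 ± 25.7 in knockout. Its log2 fold change was 2.43 ± 0.48, and DESeq2 called it. Without wild type replicate 1 the Lrrc15 value was 2.56, and without replicate 2 it was 2.33. The remaining candidates were called by neither DESeq2 nor edgeR's main fit, though with the replicate block edgeR called Gpr149 (adjusted p = 0.0486). They were Lce1h (log2 fold change 3.21 ± 0.76), the granzyme genes Gzmd (3.16 ± 1.02) and Gzme (2.58 ± 0.96), Ifi27l2b (2.92 ± 0.97), the chemokine gene Ccl6 (2.73 ± 0.84), Gpr149 (2.70 ± 0.69), Tcfl5 (2.68 ± 0.71) and Hoxc6 (2.51 ± 0.81). Gpr149, an orphan receptor gene, was at 6.33 and 10.8 CPM in wild type and 35.9 and 76.0 CPM in knockout. Gzmd and Gzme are neighbouring paralogs, and their counts are uncertain where reads were shared. Gzme had 4.20 without wild type replicate 1.

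**Figure D1:**
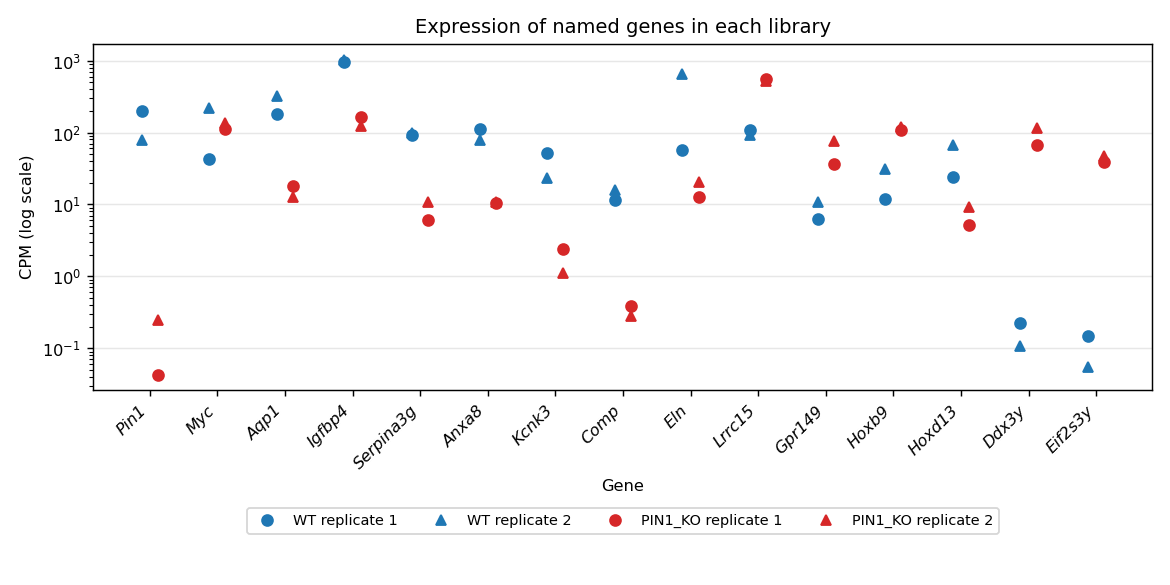
CPM of 15 named genes in each library, on a log scale (circles, replicate 1; triangles, replicate 2; blue, wild type; red, PIN1 knockout). Pin1 lies at 200 and 77.9 CPM in wild type and at 0.043 and 0.244 in knockout, while Ddx3y shows the opposite order.

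Of 42 gene lists with enough tested members, camera called 20 with its preset correlation, 8 higher and 12 lower in knockout. With an estimated correlation it called 0, with a smallest adjusted p of 0.491, and fry called 0, with a smallest adjusted p of 0.337. Fry's mixed test, of change in either direction, called 1 list, the chondrocyte and osteoblast markers (adjusted p = 0.0102). Of the 20 lists, 14 had a median of the same sign against both wild-type libraries. Their estimated correlations ran from −0.111 (adipocyte markers) to 0.652 (interferon-stimulated genes), against the preset 0.01. Lists with an estimated correlation under the preset lost their calls too. For adipocyte markers the unadjusted camera p was 0.00639 preset and 0.105 estimated. For smooth muscle markers (−0.057) it was 0.00116 and 0.0734. With an estimated correlation camera also draws on the residual degrees of freedom, which are few with 2 libraries per genotype. A lost call therefore does not measure correlation alone. The calls below hold only under the preset correlation. Camera compares a list with all other tested genes, so a call need not mean a shift from 0. Over all tested genes the median log2 difference was 0.317 against wild type replicate 1 and −0.013 against replicate 2. The polymerase I and III and G2/M lists, called lower, had means of −0.07 and −0.03. List medians are of log2 CPM differences. Over edgeR's fitted log2 fold changes, in which single genes are given, the median was 0.43 for the interferon list, −0.73 for adipocyte markers, 0.285 for immediate early genes, −0.30 for matrix genes, 0.85 for smooth muscle markers and 0.59 for leukocyte markers, each over 1.5 times from the log2 CPM median.

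MYC target genes of the nucleolus and of growth were lower as a group. The list's median log2 difference was −0.38, with 55 of 73 members lower and 18 higher, and the camera adjusted p was 1.89e-05 (adjusted p = 0.656 with an estimated correlation). The median was −0.47 against wild type replicate 1 and −0.19 against replicate 2. The list missed the threshold without wild type replicate 1, with a median of −0.19 and a camera adjusted p of 0.0563, and its median was −0.205 without knockout replicate 2. No member passed, and the smallest p belonged to Slc29a2, a nucleoside transporter gene (log2 fold change −1.89 ± 0.69), and Shmt1 of one-carbon metabolism (−1.34 ± 0.62). Next came Phb, a prohibitin gene (−1.91 ± 0.98), and Ncl, which encodes nucleolin, at 2228 and 1318 CPM in wild type and 957 and 898 in knockout. The log2 fold change was −1.25 for Slc29a2, −0.02 for Phb and −0.50 for Ncl without wild type replicate 1. RNA polymerase I and III and ribosome biogenesis genes had a median of −0.18, with 41 of 62 lower and a camera adjusted p of 0.00734 (adjusted p = 0.491 with an estimated correlation). The median was −0.07 and −0.27 against wild type replicates 1 and 2. Ubtf, a polymerase I transcription factor gene, had a log2 fold change of −1.47 ± 0.75 and Ddx56 −1.31 ± 0.68, and without wild type replicate 1 these were −0.26 and −0.30. This list, without wild type replicate 1, had a camera adjusted p of 0.0568, and without wild type replicate 2 or knockout replicate 1 it had 0.232 and 0.124, with medians of −0.06 and −0.09.

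Cell cycle lists were lower too. G1/S and DNA replication genes had a median of −0.41, with 41 of 56 lower (camera adjusted p = 6.49e-04; adjusted p = 0.927 with an estimated correlation), and −0.68 and −0.25 against wild type replicates 1 and 2. Examples were Lig1 (−1.79 ± 0.97) and Pold1 (−2.02 ± 1.11), which encode a DNA ligase and a DNA polymerase subunit. These were −0.25 and −0.02 without wild type replicate 1. The G1/S list, without wild type replicate 1, had a median of −0.245 and a camera adjusted p of 0.0780, and without knockout replicate 2 its median turned to 0.10 (0.806). Its median was −0.66 without wild type replicate 2 and −0.80 without knockout replicate 1. G2/M genes had a median of −0.18, with 37 of 53 lower (camera adjusted p = 0.0238; adjusted p = 0.949 with an estimated correlation), among them the phosphatase gene Cdc25b (−1.67 ± 0.65) and Kif23 (−0.85 ± 0.55, and −0.54 without knockout replicate 2). The G2/M median was −0.06 and −0.28 against wild type replicates 1 and 2. This call ended without wild type replicate 2, with a median of −0.05 (camera adjusted p = 0.358), and the direction turned without knockout replicate 2, to a median of 0.19 (0.329). The median was −0.275 without wild type replicate 1 and −0.60 without knockout replicate 1. Targets of p53 were higher, with a median of 0.64 and 28 of 40 higher (camera adjusted p = 0.0103; adjusted p = 0.750 with an estimated correlation), and 0.94 and 0.37 against wild type replicates 1 and 2. Pmaip1, a pro-apoptotic gene, had a log2 fold change of 1.53 ± 0.57 and Mdm2, the p53 ubiquitin ligase gene, 1.28 ± 0.62. Ak1 had 0.96 ± 0.45 and Pltp −1.61 ± 0.70. Mdm2 had 0.76 without knockout replicate 2, and Pltp −0.60 without wild type replicate 1, where the p53 list had a median of 0.38. The list's camera adjusted p was 0.248 without wild type replicate 2 and 0.0562 without knockout replicate 2. Replication-dependent histone genes, whose RNAs mostly lack poly(A) tails, had a median of 2.09, with 11 of 13 tested members higher (camera adjusted p = 3.97e-04; adjusted p = 0.491 with an estimated correlation), and 2.37 and 1.72 against wild type replicates 1 and 2. Hist1h1c had a log2 fold change of 2.11 ± 0.56 and Hist1h2bc 1.79 ± 0.50. The histone list was not called without wild type replicate 2 (0.523) or knockout replicate 2 (0.129), and without a filter its median was 0.55 over 38 members (0.0153).

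HOX genes, which record position along the embryo, were higher. The median was 1.53, with 28 of 35 higher (camera adjusted p = 7.97e-05; adjusted p = 0.491 with an estimated correlation). It was 2.62 against wild type replicate 1 and 1.31 against replicate 2, and camera called the list in each fit that left out a library. Several members had 0 counts in wild type replicate 1, among them Hoxb2 and Hoxb3, which had 195 and 99 counts in replicate 2. Such zeros enlarge the medians that use replicate 1. Hoxb9 was at 11.8 and 31.2 CPM in wild type and 108 and 119 CPM in knockout (log2 fold change 2.40 ± 0.66). Hoxc6 had a log2 fold change of 2.51 ± 0.81. Members at the 5′ end of the Hoxd cluster went the other way, with Hoxd13 at −2.64 ± 0.78 and Hoxd12 at −3.14 ± 1.18. Hoxd13 had −1.695 without wild type replicate 2.

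**Figure D2:**
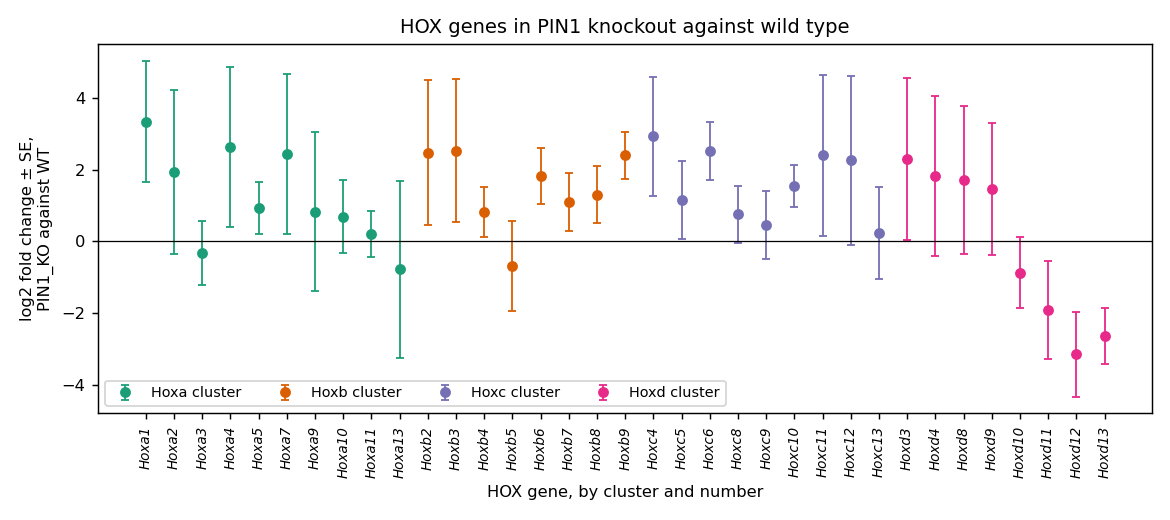
Log2 fold change of the 35 tested HOX genes in PIN1 knockout against wild type, ordered by cluster and number, with SE bars (n = 2 per genotype). Points above 0 are higher in knockout, and Hoxd10 to Hoxd13 lie below 0, as do Hoxa3, Hoxa13 and Hoxb5.

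Markers of contractile cells were higher. Smooth muscle and pericyte markers had a median of 1.28, with 13 of 16 higher (camera adjusted p = 0.00486; adjusted p = 0.491 with an estimated correlation), and 1.09 and 1.02 against wild type replicates 1 and 2. Myh11, the smooth muscle myosin heavy chain gene, was at 8.26 and 7.88 CPM in wild type and 39.8 and 28.1 CPM in knockout (log2 fold change 2.07 ± 0.56), and Lmod1 had 1.65 ± 0.47. Mcam, a pericyte surface protein gene, had 1.62 ± 0.52. Targets of SRF and MRTF, the actin-regulated transcription factors, had a median of 0.50, with 20 of 29 higher (camera adjusted p = 0.0238; adjusted p = 0.491 with an estimated correlation), and 0.42 and 0.34 against wild type replicates 1 and 2. They included Lmod1, which is on both lists, Tpm1 (1.01 ± 0.45) and Filip1l (1.29 ± 0.87), which had 0.57 without wild type replicate 1 and 2.87 without replicate 2. Without wild type replicate 2 neither list was called (0.523 and 0.752), and the SRF list then lay below the other genes. It was not called without knockout replicate 1 (0.188) or without a filter (0.147) either.

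Matrix and skeletal markers were lower. Extracellular matrix and collagen genes had a median of −0.18, with 42 of 64 lower and 22 higher (camera adjusted p = 0.00486; adjusted p = 0.777 with an estimated correlation). The median was −0.32 against wild type replicate 2 and near 0 against replicate 1. Eln, which encodes elastin, had 765 and 12196 counts in wild type and 298 and 593 in knockout, and DESeq2 called it. Its log2 fold change was −1.75 without wild type replicate 2. Fmod, which encodes fibromodulin, had a log2 fold change of −2.13 ± 0.54 and Mfap4 −1.61 ± 0.49, whereas the collagen crosslinking enzyme gene Loxl2 was at 300 and 480 CPM in wild type and 1135 and 1587 CPM in knockout. Chondrocyte and osteoblast markers had a median of −0.70, with 10 of 14 lower (camera adjusted p = 0.00486; adjusted p = 0.491 with an estimated correlation; fry's mixed adjusted p = 0.0102). The median was −1.17 and −0.54 against wild type replicates 1 and 2. Comp, a cartilage matrix gene, averaged 13.8 ± 2.99 against 0.333 ± 0.076 CPM and passed when adjusted over the list alone (edgeR adjusted p = 0.0356). The collagen genes Col2a1 (−3.41 ± 0.97) and Col10a1 (−2.83 ± 0.89) did not. Adipocyte markers had a median of −0.26 (−0.73 over edgeR's fitted fold changes), with 7 of 9 lower (camera adjusted p = 0.0168; adjusted p = 0.491 with an estimated correlation), and −1.28 and −0.35 against wild type replicates 1 and 2. Plin4, a lipid droplet gene, summed to 431 counts in wild type and 11 in knockout, and Fabp4 had −3.03 ± 0.86 and Lpl −1.20 ± 0.48. Epithelial markers had a median of −0.74, with 11 of 15 lower (camera adjusted p = 0.0118; adjusted p = 0.491 with an estimated correlation), and −1.39 and −0.47 against wild type replicates 1 and 2. Krt15 had 101 and 213 counts in wild type and 0 and 11 in knockout, and Krt7 had a log2 fold change of −3.25 ± 1.19, which was −0.97 without wild type replicate 1. Col10a1 had −1.84 and Fabp4 −1.83 without wild type replicate 2. The epithelial list, without wild type replicate 1, had a camera adjusted p of 0.0541, and the matrix and chondrocyte medians were then −0.31 and −1.16. Without wild type replicate 2 the matrix, chondrocyte, adipocyte and epithelial lists had camera adjusted p of 0.406, 0.232, 0.248 and 0.0683, with medians of 0.01, −1.06, −1.27 and −1.36. The matrix and epithelial medians were −0.115 and −1.17 without knockout replicate 1, and the adipocyte and epithelial medians −0.165 and −0.22 without knockout replicate 2. With the GC and length correction the adipocyte and epithelial lists had camera adjusted p of 0.0554 and 0.144. Without a filter they had 0.0747 and 0.103, with medians of −0.11 and 0.22, and the chondrocyte median was −0.03 over 22 members (0.0399). With the stricter filter the epithelial median was −2.16 over 8 members (0.00106).

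Leukocyte markers were higher, with a median of 0.89 and 24 of 26 higher (camera adjusted p = 7.97e-05; adjusted p = 0.491 with an estimated correlation). The median was 1.52 and 0.70 against wild type replicates 1 and 2. Lyz2, which encodes lysozyme, was at 163 and 274 CPM in wild type and 643 and 776 CPM in knockout (log2 fold change 1.70 ± 0.53). Fcgr3, an Fc receptor gene, had 1.97 ± 0.61 and the complement gene C1qc 1.58 ± 0.61. Camera called this list in each fit that left out a library, and its median was 1.81 without wild type replicate 2.

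Several called lists rested on wild type replicate 1. Cytosolic ribosomal protein genes had a median of −0.69 (camera adjusted p = 2.07e-05; adjusted p = 0.927 with an estimated correlation), which was −1.63 against replicate 1 and 0.18 against replicate 2. The 2 members of smallest p were Rpl15 (−1.17 ± 0.51) and Rps6 (−1.99 ± 1.01). Nuclear-encoded oxidative phosphorylation genes had a median of −0.36 (camera adjusted p = 0.00115; adjusted p = 0.949 with an estimated correlation), which was −1.12 and 0.33 against replicates 1 and 2. Ndufa6 had 1.13 ± 0.58 and Cycs −1.99 ± 1.03. Interferon-stimulated genes had a median of 1.37, and of 0.43 over edgeR's fitted fold changes (camera adjusted p = 0.00222; adjusted p = 0.949 with an estimated correlation), and the first was 3.59 and −0.49 against replicates 1 and 2. Psmb10 (−2.07 ± 1.06) and Ifi35 (−1.35 ± 0.77) had the smallest p and ran against the list. Immediate early genes had a median of 0.61 (camera adjusted p = 0.0357; adjusted p = 0.949 with an estimated correlation), which was 1.31 and −0.08 against replicates 1 and 2. Phlda1 had a log2 fold change of 1.44 ± 0.51, Arc −2.52 ± 0.97 and Plk3 1.24 ± 0.60. Genes near Pin1 on chromosome 9 had a median of −0.58 (camera adjusted p = 0.00115; adjusted p = 0.750 with an estimated correlation), and −1.04 and −0.04 against replicates 1 and 2, with Col5a3 at −1.81 ± 0.68 and Tmed1 at −1.52 ± 0.78. Peptidyl-prolyl isomerases, with Pin1 among them, had a median of −0.15 (camera adjusted p = 0.0223; adjusted p = 0.491 with an estimated correlation), which was −0.22 against replicate 1 and near 0 against replicate 2. This list holds the deleted gene and no test was run without it, and its mean was −0.57 against the median of −0.15. Ppih had −5.49 ± 1.91, at 15.3 and 0.804 CPM in wild type, and −2.18 with the mean over transcript rows. Without wild type replicate 1 the log2 fold change was −0.095 for Rps6, −0.27 for Cycs, 0.11 for Psmb10, −0.12 for Ifi35, 0.81 for Plk3, −0.99 for Col5a3, −0.36 for Tmed1 and −2.17 for Ppih. It was −0.91 for Arc and 1.88 for Plk3 without wild type replicate 2. In the fit that left out wild type replicate 1, the ribosomal, immediate early, chromosome 9 and isomerase lists had camera adjusted p of 0.0729, 0.198, 0.303 and 0.195, with medians of 0.20, −0.07, −0.06 and 0.009. The oxidative phosphorylation and interferon lists were then called in the opposite direction, with 5.03e-04 and 2.66e-04 and medians of 0.34 and −0.485. Without wild type replicate 2 the ribosomal, oxidative phosphorylation, interferon, immediate early and chromosome 9 medians were −1.60, −1.105, 3.64, 1.32 and −1.025. Without knockout replicate 1 the ribosomal, oxidative phosphorylation, interferon and isomerase medians were −1.16, −0.67, 2.27 and −0.37. Without knockout replicate 2 the immediate early, interferon and oxidative phosphorylation lists were not called (0.148, 0.502 and 0.0562), with medians of 0.33, 0.44 and −0.09, and the ribosomal, chromosome 9 and isomerase medians were −0.18, −0.35 and −0.015. The immediate early list was not called without a filter (0.122), nor the isomerase list with the stricter filter (0.116), and the isomerase median was −0.05 without a filter.

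**Figure D3:**
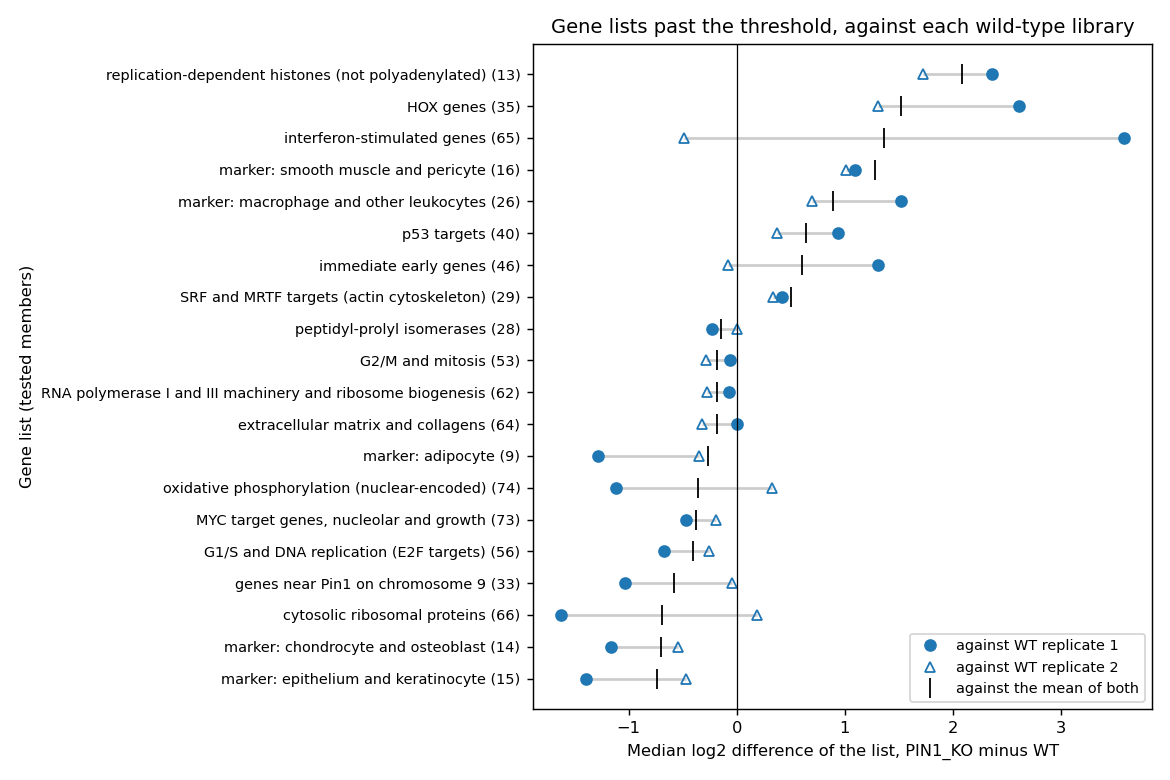
Median log2 difference, PIN1 knockout minus wild type, of the 20 lists that camera called with its preset correlation, against wild type replicate 1 (filled circles), replicate 2 (open triangles) and the mean of both (bars). The interferon list spans 3.59 to −0.49, whereas the smooth muscle and pericyte list lies at 1.09 and 1.02.

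Camera did not call the insulin and IGF signalling list or the NF-kB list, each holding genes far from 0. In the insulin list Igfbp2 (−2.31 ± 0.56) and Foxo1 (−1.84 ± 0.56) were lower and Txnip (1.99 ± 0.60) higher, beside Igfbp4. In the NF-kB list Mmp3, a matrix protease gene (−2.15 ± 0.54), Cx3cl1 (−1.56 ± 0.51) and Il1rl1 (−3.11 ± 1.04) were lower, beside Serpina3g. Il1rl1 had −1.15 without wild type replicate 2. Without wild type replicate 1 camera called both lists lower, with adjusted p of 0.00549 and 0.00275. In that fit it also called the TGF-beta (0.00531), nuclear pore (0.0307), fibroblast (0.00301) and endothelial (0.00156) lists lower, and the cholesterol (0.00151), glycolysis (2.60e-04) and skeletal muscle (2.54e-04) lists higher. The ATF4 list was called lower without knockout replicate 1 (0.00204) and higher without knockout replicate 2 (0.0189). Without knockout replicate 1 the nucleotide and one-carbon list was called lower (0.0101) and the YAP list higher (0.0187), and without knockout replicate 2 the glycolysis list was called higher (0.0239). For the insulin, TGF-beta, Wnt, Notch, ATF4, cholesterol, NRF2, nuclear pore, fibroblast, endothelial, neural, mesothelial and skeletal muscle lists, none of them called with the 4 libraries, the median, mean and test differed in sign. The erythroid and mitochondrially encoded lists had 0 tested members.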

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

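The settings added after the data were seen are the GC and length correction, that correction with the block, the mean over transcript rows and the voom quality weights. Across settings, 1121 of the comparisons of named genes with the main result kept side and direction, 164 gained a call and 8 turned direction. The main fit called 0 genes, so kept means uncalled in both fits with the same sign. It does not measure how firm a call is. For the described lists the figures were 220 kept, 52 lost, 1 gained and 12 turned relative to the other genes. Apart from fits without a library and the estimated correlation, these ended calls: no filter for the SRF, adipocyte, epithelial and immediate early lists, the stricter filter for the isomerase list, the GC and length correction for the adipocyte and epithelial lists, that correction with the block for the epithelial list (camera adjusted p = 0.0974) and the replicate block for the G2/M list (0.134). The histone list kept fewer than 5 tested members with the stricter filter and was not tested there. The nucleotide and one-carbon list was called with DESeq2 size factors (0.0490), without a filter (0.0196), with the GC and length correction (0.0104) and with that correction and the block (0.00750).

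The count of changed genes was 0 in the main fit, with both other scalings, both filters, limma-voom with and without quality weights, the GC and length correction, the mean over rows, limma on the scaled signal, and the other thresholds. It was 19 with DESeq2. With a library left out it ran from 2 to 6363, and a genotype left with 1 library was assumed to vary like the other. The number of lists ran from 10 to 21 with a library left out, and was 0 with an estimated correlation, 0 with fry and 1 with fry's mixed test.

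Replicate numbers are shared by label only. The differences between replicates 1 and 2 correlated at 0.55 between genotypes across genes, from 2 pairs. Split by replicate number, 1110 genes had an unadjusted p under 0.05, against 166 by genotype and 0 by the other split, and edgeR called 0 genes in each. With the replicate block 32 genes were called, 15 of them also called by DESeq2, and 26 with the GC and length correction and the block. Pin1 passed in these fits (−9.65 and −9.97), and with DESeq2 (−9.90). It ran from −11.44 to −8.95 with a library left out, not passing without knockout replicate 1. Myc was 0.34 with the block, 0.045 with the correction and block, 0.31 with limma-voom, 0.31 with quality weights and 0.40 on the scaled signal. It ran from −0.82 to 1.54 with a library left out. The causes were not tested.

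The median of the MYC target list was −0.38 with an estimated correlation and ran from −0.49 to −0.19 with a library left out. Ranges with a library left out, for results whose value, or direction relative to the other genes, turned in at least 1 such fit, were as follows. Psmb10 ran from −2.89 to 0.11, and was −1.36 with limma-voom, −1.34 with quality weights and −1.34 on the scaled signal. The SRF list ran from 0.35 to 0.51 and turned only relative to the other genes. Ribosomal proteins ran from −1.60 to 0.20, oxidative phosphorylation from −1.11 to 0.34, interferon genes from −0.49 to 3.64, immediate early genes from −0.068 to 1.32, G1/S genes from −0.80 to 0.10, G2/M genes from −0.60 to 0.19, matrix genes from −0.31 to 0.01 and isomerases from −0.37 to 0.009. The insulin list ran from −0.20 to 0.65 and was 0.16 with the stricter filter. The NF-kB list ran from −0.31 to 1.33 and was 0.13 with the stricter filter. Without a filter it was 0.55 and turned only relative to the other genes. The GC and length correction moved the median of all genes from 0.05 to −0.29, so changes in that fit are relative to it. Named genes moved by over 1.5 times there were Myc (−0.27), Ncl (−2.40), Lpl (−2.39), Cycs (−3.63), Rpl15 (−2.065), Kif23 (−1.725), Tpm1 (0.635), Pmaip1 (0.57) and Mdm2 (0.64). Medians of described lists so moved were insulin −0.25, NF-kB 0.105, SRF 0.07, immediate early 0.27, p53 0.37, interferon 0.86, MYC targets −0.69, polymerase I and III −0.60, G1/S −0.92, G2/M −0.72, matrix −0.41, isomerases −0.47 and chondrocyte −1.08. With upper-quartile scaling Myc was −0.019, the polymerase, G2/M and matrix medians were −0.10 and the isomerase median −0.06. Depth limits genes near 0 counts, such as Pin1l, whose ratio has a counting interval of 101 to 22400.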

Other observations

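Tests of the X-linked escape genes, of positional genes and of abundant genes were fixed before their results were seen. The others were chosen after the result was seen.

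Among transcription factor genes of embryonic position outside the HOX clusters, the genotypes did not overlap for 13 of 35 tested. That is near the 33.3% that chance gives, and the share over all tested genes was 26.71%. The genes of smallest p are given here, while others lay near 0, such as Tbx2 (log2 fold change 0.21) and Six1 (0.07). Msx1, a limb and skull mesenchyme gene, was at 7.30 and 58.4 CPM in wild type and 3.83 and 2.97 in knockout (log2 fold change −3.27 ± 1.14, SE). Emx2 was at 3.72 and 13.5 CPM in wild type and 34.0 and 48.0 in knockout (2.25 ± 0.81). Pitx1, a hindlimb gene, had −1.39 ± 0.80 and Meis1 1.13 ± 0.54. None passed the edgeR threshold over all genes. Msx1 had −1.09 and Emx2 3.47 without wild type replicate 2, and Pitx1 had −0.92 without knockout replicate 2.

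Wild type replicate 1 stood apart from the other libraries. After the GC and length correction its highest correlation with another library was 0.833, below the lowest of 0.934 among the others, which argues against that trend as the whole explanation. Thinned to its total, the other libraries still detected at least 14507 genes against 11387, which argues against depth. Few starting molecules were predicted to spare abundant genes. Yet among 259 genes of at least 500 CPM its median deviation was 3.44 times the highest of the others. Those genes were chosen on a mean that includes this library, and uneven amplification may also move abundant genes, so the test does not decide. In addition, 240 genes had 0 counts in it and at least 100 in each other library, a loss seen for 0 genes in the other libraries. Few starting molecules, a different cell state, uneven amplification and RNA quality stay open, as no test here separates them.

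Y-linked RNAs were seen in the knockout libraries. Reads of the X-linked partners counted for the Y-linked genes would give like shares in both genotypes, but the Y-linked share was at least 114 times higher in knockout in each of the 4 pairs, which argues against that source. In wild type Ddx3y, Eif2s3y, Uty and Kdm5d summed to 5, 3, 2 and 6 counts. In knockout they summed to 4919, 2282, 632 and 738. The counts point to wild-type cultures with few or no Y-bearing cells and knockout cultures that held them, as from embryos of different sex. The 4 X-linked escape genes Kdm6a, Ddx3x, Eif2s3x and Kdm5c had a median log2 fold change of −0.33, at percentile 16.7 of random X-linked sets. The escape genes alone do not decide on sex, as their median was 0.92 against wild type replicate 1 and −0.99 against replicate 2. All 4 were lower in knockout than in wild type replicate 2 (−1.27, −1.04, −0.95 and −0.71, in that order). Against replicate 1 only Kdm5c was lower (−0.95), and there Kdm6a had 3 counts, against 550 in replicate 2. Y-linked RNA divided the libraries as genotype did, so effects of sex and of genotype cannot be told apart in these 4 libraries.

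HOX genes were higher in knockout. With the GC and length correction the HOX median was 1.20 (camera adjusted p = 1.13e-06 with the preset correlation). This argues against that trend as the whole explanation. Without the correction, the call ended with an estimated correlation (camera adjusted p = 0.491). Against wild type replicate 2 alone the median was 1.31 (quartiles 0.47 to 1.86), with 27 of 35 members higher, which argues against wild type replicate 1 as the sole source. Cultures that hold different body regions may also shift HOX genes, and positional genes outside the clusters had a median absolute log2 fold change of 0.88 against 0.67 in random sets, at percentile 91.4, which does not decide it. An effect of genotype, of sex or of the embryos used stays open.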
